A study of Mus musculus with 4 samples.

How the data were processed

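Gene expression was measured by 1-colour (Cy3) hybridisation to Agilent mouse oligonucleotide arrays. The 4 arrays comprised 2 of WT and 2 of Bach2KO alveolar macrophage RNA, all on 1 slide. Per the labels' protocols, cells from 8 WT and 4 Bach2KO mice were sorted by flow cytometry, 1 RNA sample per genotype was divided in 2, and each part was amplified and labelled separately. The series design text gives 3 Bach2KO mice, and which number holds was not settled. Arrays were assigned to genotypes from the sample titles. The gate used for sorting is not given in the sources used here.

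The scanner files hold spot intensity on a linear scale, processed with Agilent Feature Extraction 10.7.3.1 per the file headers, whereas the submitters' processing notes name version 9.1. The processed intensity was background-subtracted and detrended within each array and was not normalized between arrays, per the file headers. The deposited value table holds log2 values. Set against the scanner files, each column was the log2 processed signal of its own array minus a constant close to that array's 75th percentile, with no centring of genes and with higher values for brighter probes. For probes with 1 spot the SD of the difference was between 3.2e-07 and 3.5e-07, and the column medians were -3.58, -3.67, -3.53 and -3.45. Its scale, centring and direction were thereby settled.

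From the processed signals, spots of a probe were averaged on the log2 scale, after control spots and spots marked as feature outliers had been left out (109, 120, 133 and 136 outlier spots on the arrays in order, of 43020 non-control spots). No spot was saturated on any array (0 of 43020). Each array's 75th percentile was then subtracted. Probes entered if well above background on both arrays of at least 1 genotype. The design names probes by accession, and gene symbols were taken through unversioned accessions from a RefSeq gene table of assembly GRCm38.p6. The array design was built on mm9, so no coordinates are given. Of 39429 probes 26055 had 1 symbol, 0 had several and 13374 had none, which left 19751 genes on the array and 15124 measured. The probe with the highest mean signal stood for its gene. Among 478 called genes with several measured probes, all probes gave the same call for 285, and another probe differed at least 2-fold the other way for 5. Of the 5 probes of Patj, 3 gave its call.

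The design, the gene lists and the alternatives were fixed before the data were examined, except the spike-in scaling and a crossed replicate block. A gene was called higher or lower where all 4 pairs of a Bach2KO and a WT array differed at least 2-fold in that direction. Where it was not well above background on both arrays of a genotype, its lower bound also had to reach 2-fold. This is a rule of size and not a test. limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg) was run on the same values as a description of technical precision. For each of 32 gene lists, the median difference was placed among 10000 random lists of the same size matched on mean signal in 20 bins, and a list stood apart at or below percentile 2.5 or at or above 97.5. The lists covered macrophage identity, activation states, chemokines, receptors, lipid and surfactant metabolism, lysosomes, iron, transcription factors of the AP-1, Maf and CNC families, matrix, proliferation, interferon response, antigen presentation, phagocytosis, glycolysis, endoplasmic reticulum stress, markers of other cell types, sex-linked genes and reference genes, and 72 genes were in more than 1 list.

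Named genes were Bach2, the 10 largest and 10 smallest differences among called genes well above background on all 4 arrays, the 5 largest bounds each way, up to 4 called members per list by size (or, with none called, the 2 with the highest signal), and 17 genes chosen for their roles in alveolar macrophages. Predicted and clone-named genes were counted and not named, and 1 gene that the rule selects is not reported here. Genes with near-identical copies, such as Chil3, the Klra receptors and the Ear family, are uncertain because a probe may bind several copies.

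Alternatives were median centring, quantile normalization, normexp background correction with an offset of 50 followed by either scaling, the deposited value table, no filter on dim probes, a filter requiring all 4 arrays, keeping outlier spots, the mean of a gene's probes, thresholds of 1.5-fold and 3-fold, the 2-fold rule on array means, the replicate number as a block, and leaving out each array in turn. The normexp correction used median spot signals, as mean spot signals were not used here. The spike-in probes were the E1A set, 9 of which were well above background on all arrays.

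The procedure was tested on simulated data with the 15124 measured genes and the technical spread of these arrays. The rule called 0 of 50 genes planted at 1.5-fold, 7 of 50 at 2-fold, 50 of 50 at 4-fold and 50 of 50 at 8-fold, and 1 of 14924 unchanged genes. The corresponding numbers for limma were 4, 33, 49 and 50, and 6 unchanged genes. Changes were planted only in genes above a set mean signal, so recovery of genes near background in 1 genotype was hardly tested. The simulated noise held no spread between RNA samples, so the unchanged genes called describe labelling and hybridisation noise only. Of 100 unchanged lists 8 stood apart. A list with every member shifted alike lay at percentile 100. That was near certain where nearly all other genes varied by technical noise alone, so it does not measure power in the real data. The number of arrays and the single RNA sample per genotype limit the precision. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. Probes without a gene symbol were left out of the comparison.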

Results

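Gene expression was measured in alveolar macrophages, the resident phagocytes of the airspaces that take up and degrade surfactant, from wild-type (WT) mice and from mice lacking Bach2 (Bach2KO). Bach2 is a transcription repressor of the CNC leucine zipper family that binds Maf recognition elements. The comparison asked how the transcripts of these macrophages differed without Bach2, in a study of surfactant homeostasis. Cells were pooled from 8 WT mice and from 3 Bach2KO mice according to the series design text, or 4 according to the treatment protocol, and were sorted by flow cytometry. A single RNA sample per genotype was divided in 2 before amplification and labelling, which gave 2 WT and 2 Bach2KO arrays. The arrays of a genotype are technical repeats, so the difference between genotypes has no replicate check and no p-value, and the SDs written after ± are over 2 arrays of 1 RNA sample. Between 27163 and 27962 of the 39429 probes were well above background on each array, and 15124 genes were measured. The 75th percentile of the processed signal was 1267 and 1513 on the WT arrays and 1036 and 979 on the Bach2KO arrays. Values are given as log2 signal relative to that percentile, and a gene is called higher or lower where it differed at least 2-fold in that direction in each of the 4 array pairs.

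Bach2 itself was near the detection limit in both genotypes. Its only probe, assigned to transcript NM_001109661, had log2 signals of -6.32 and -6.28 on the WT arrays and of -5.16 and -8.13 on the Bach2KO arrays. The probe was well above background on WT array 2 and Bach2KO array 1, and not on the other 2 arrays. Whether it lies in the deleted part of the gene is not given in the sources used here, so Bach2 gave no check of the genotype labels.

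The genes with the largest differences between the RNA samples included those of secreted factors, receptors and lipid-handling proteins. Fstl1, which encodes a secreted follistatin-related glycoprotein, had a log2 signal of -3.06 ± 0.04 in WT and 6.45 ± 0.07 in Bach2KO (SD, n = 2 arrays), a 729-fold higher signal. Inhba, the activin A subunit gene, was 363-fold higher, Arg1, which encodes the arginine-degrading enzyme arginase 1, 279-fold higher, and the growth factor genes Pdgfa and Csf1 244-fold and 159-fold higher. Heparanase (Hpse) was 199-fold higher, the mannose 6-phosphate receptor gene Igf2r 179-fold and the B cell adaptor gene Blnk 165-fold. In the other direction, the fatty acid-binding protein gene Fabp1 fell from 5.64 ± 0.19 to -1.57 ± 0.08, a 148-fold lower signal. The complement C5a receptor gene C5ar1 was 101-fold lower, the apolipoprotein gene Apoc1 73.4-fold lower and Cidec, which encodes a lipid droplet protein, 68.3-fold lower.

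Some transcripts were well above background in 1 genotype alone and therefore have only a lower bound, computed against the higher of the dim probe's own signal and the lowest signal well above background on the same array. The retinol-binding protein gene Rbp4 was at least 3550.3-fold higher in Bach2KO, the neuropeptide gene Npy at least 515-fold, the interleukin 7 receptor gene Il7r at least 361-fold and Rai14 at least 334-fold. The serotonin receptor gene Htr2c was at least 129-fold lower by its brighter probe, with a difference of -2.22 for its other probe, the integrin gene Itgad at least 104-fold and the epithelial adhesion gene Epcam at least 98.1-fold. Such a gene was called where its bound also reached 2-fold.

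By the same rule 1266 genes were higher in Bach2KO, 222 of them known only as a bound, and 892 were lower, 87 of them as a bound. The remaining 12966 genes met neither condition, and 58.7% of the calls were higher. At least 8-fold differences in the array means were seen for 352 of the higher and 136 of the lower genes. Arrays of the same RNA differed at least 2-fold for 135 genes in WT and 92 in Bach2KO, and the other 2 ways of dividing the 4 arrays into pairs called 1 and 5 genes. Those divisions mix the genotypes, so a gene that differs between the RNA samples can hardly be called by them. Their counts therefore give no background for the calls. The SD over genes of the difference was 0.26 between the WT arrays, 0.21 between the Bach2KO arrays and 1.16 between genotypes (log2). With limma and Benjamini-Hochberg adjustment at 0.05, which set the 2 RNA samples, not the genotypes, against labelling and hybridisation spread, 9784 genes differed, 5098 higher and 4686 lower. Scaling to the spike-in probes, an alternative chosen after seeing the data, lowered every difference by 0.72. It gave 628 higher and 3192 lower genes, 16.4% of the calls higher, with a median over all genes of -0.66 in place of 0.06. Because every gene moved alike, the percentile of each gene list among matched lists stayed the same. The arrays of each genotype occupied adjacent positions on 1 slide, so position and genotype cannot be told apart.

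**Figure D1:**
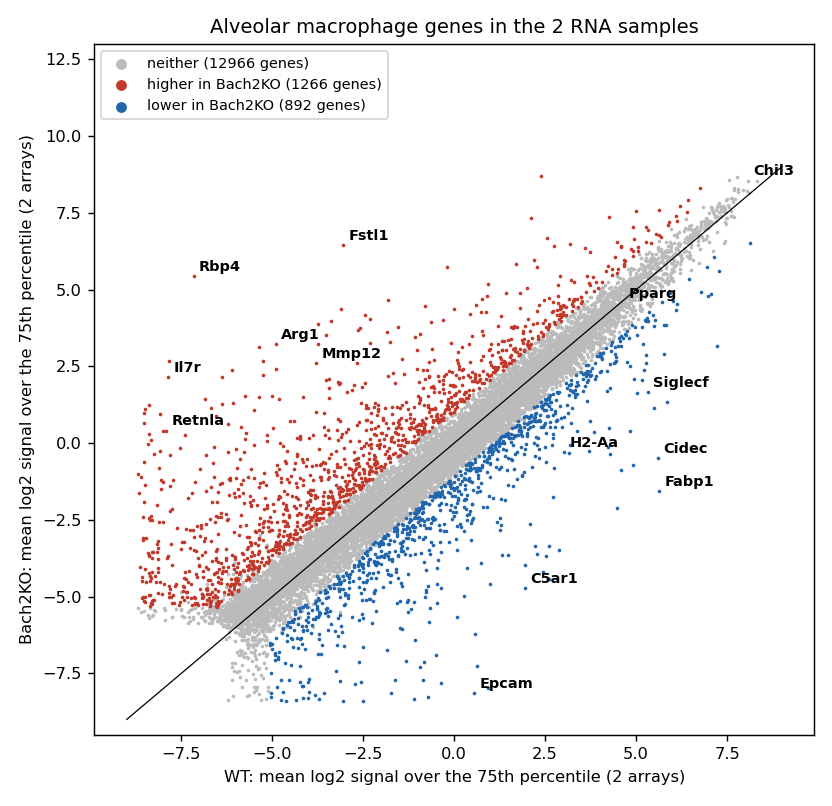
Mean log2 signal over the 75th percentile of 15124 genes in WT (horizontal axis) and Bach2KO (vertical axis), each over 2 technical arrays, with the diagonal drawn for equal signal. The 1266 genes higher in Bach2KO are red, the 892 lower are blue and the others grey, under 75th-percentile scaling; spike-in scaling gave 628 and 3192.

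Genes of alternative macrophage activation, the program induced by interleukin 4, were higher as a group. Of 28 measured members 13 were higher and none lower, and the remaining 15 met neither condition, against 10 higher and 4 lower with spike-in scaling. Beside Arg1, Retnla, which encodes the secreted resistin-like molecule alpha, was at least 108-fold higher, and the coagulation factor gene F13a1 at least 24.9-fold. Gas6, a bridging ligand of the TAM receptors, rose from -4.71 ± 0.18 to -0.11 ± 0.08. The chitinase-like gene Chil3, whose probe may also bind near-identical copies, had signals of 8.06 ± 0.21 and 8.55 ± 0.02, a difference of 0.49 that met neither condition and was -0.23 with spike-in scaling. The list's median difference was 1.29, or 0.96 with bounded genes at their bound, at percentile 100 of 10000 random lists matched on signal. The median was 0.57 with spike-in scaling, 0.78 with normexp and the 75th percentile and 0.83 where all 4 arrays had to be above background. Markers of monocytes and interstitial macrophages moved with this group, with 11 of 24 measured members higher and 3 lower.

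Classical activation genes went both ways. Of 24 measured members 9 were higher, 3 lower and 12 neither, with a median difference of 0.35 at percentile 98.8, which was -0.37 with spike-in scaling, and the list did not stand apart where all 4 arrays had to be above background (96.1). The protein kinase C substrate gene Marcks was 133-fold higher, the cytokine signalling inhibitor gene Socs3 6.16-fold higher and the cytokine gene Il6, not well above background in WT, at least 3.58-fold higher, a call of Il6 that ended with normexp background correction (1.06). The formyl peptide receptor gene Fpr2 was 5.54-fold lower, and inducible nitric oxide synthase (Nos2) had a log2 signal of -2.08 ± 0.09 in WT and -2.03 ± 0.15 in Bach2KO. Chemokine genes had a median difference of 1.19 (percentile 100), with 13 of 22 higher, 3 lower and 6 neither, and of 0.47 with spike-in scaling. The monocyte-attracting chemokine gene Ccl2 rose from -3.52 ± 0.04 to 2.06 ± 0.04, Ccl3 was 19.9-fold higher, the eosinophil-attracting Ccl24 21.7-fold higher, and Ccl7 at least 52.4-fold higher.

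Genes that mark alveolar macrophages were lower more often than higher. Of 31 measured members 11 were lower, 5 higher and 15 neither, with a median of -0.14 at percentile 0.54 of matched lists, whose own median was 0.14. The median was -0.28 with median centring, -0.34 with quantile normalization and -0.86, with 3 higher and 14 lower, with spike-in scaling. Siglecf, the sialic acid-binding lectin used to identify these cells, fell from 5.31 ± 0.10 to 1.66 ± 0.08, 12.6-fold. The scavenger receptor gene Marco was 3.61-fold lower and the keratin gene Krt79 16.8-fold lower. Fabp4, another fatty acid-binding protein gene of these cells, was 3.00-fold higher, but not called with spike-in scaling (0.87). Pparg, the nuclear receptor gene required for alveolar macrophage development, differed by -0.10, with array pairs from -0.15 to -0.05.

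Genes of surfactant catabolism and cholesterol efflux did not stand apart as a group. Of 31 measured members 4 were higher, 5 lower and 22 neither, and the median of 0.10 lay at percentile 55.6 and turned negative with median centring, quantile normalization and spike-in scaling. The receptor subunit genes for GM-CSF, the cytokine that drives surfactant clearance, differed by 0.10 (Csf2ra) and 0.15 (Csf2rb), and by -0.61 and -0.56 with spike-in scaling. The cholesterol exporter gene Abca1 was 5.63-fold lower (1.65 ± 0.07 and -0.85 ± 0.06), and the LDL receptor-degrading ligase gene Mylip 7.51-fold lower. Abcg1, a second cholesterol exporter gene, differed by -0.60 and met neither condition, although it did with spike-in scaling (-1.32). The scavenger receptor genes Msr1 and Cd36, which mediate uptake of modified lipoproteins, were 8.86-fold and 4.03-fold higher.

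**Figure D2:**
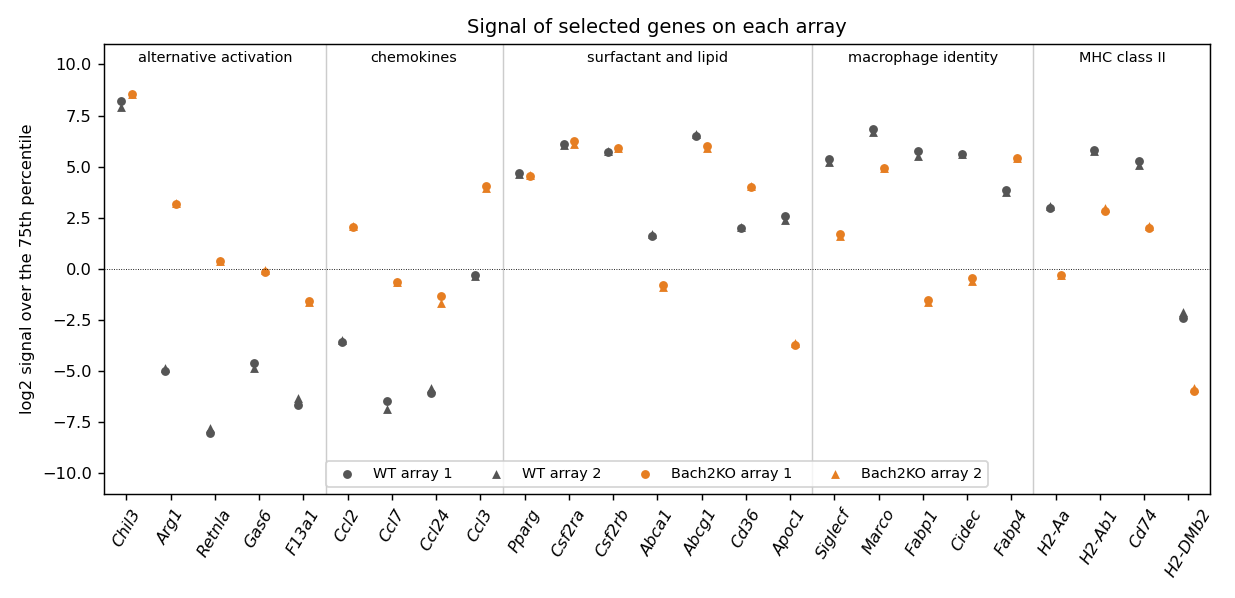
Log2 signal over the 75th percentile of selected genes on each of the 4 arrays, with WT arrays in grey and Bach2KO arrays in orange, circles for array 1 and triangles for array 2. Arrays of a genotype nearly overlap; Pparg, Csf2ra and Csf2rb lie close in both genotypes (differences of -0.10, 0.10 and 0.15, and -0.82, -0.61 and -0.56 with spike-in scaling), whereas Arg1, Siglecf and H2-Aa lie far apart.

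Cholesterol synthesis genes were higher by small amounts. With spike-in scaling their median was not above 0, although the list still stood above matched lists. Of 26 measured members 7 were higher, none lower and 19 neither. The median was 0.68, and -0.04 with spike-in scaling, where no member was called, at percentile 100 with either scaling. Dhcr7, which catalyses the last step of cholesterol synthesis, was 3.09-fold higher and the farnesyl diphosphate synthase gene Fdps 2.72-fold higher. Fatty acid and triglyceride synthesis genes split, with 8 of 34 higher, 6 lower, 20 neither and a median of 0.03 (percentile 33.6) that was negative with median centring and spike-in scaling. The acyl-CoA synthetase gene Acsl3 was 7.81-fold higher and the fatty acid elongase gene Elovl6 9.15-fold lower. Fatty acid oxidation genes were lower as a group, with a median of -0.27 at percentile 0.55, although 1 of 27 members was higher, 3 lower and 23 neither, against 10 lower and a median of -0.99 with spike-in scaling and a median of -0.40 with median centring. Cpt1a, which encodes the enzyme that commits fatty acids to mitochondrial import, was 2.21-fold lower and the peroxisomal enzyme gene Ehhadh 2.87-fold lower.

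Lysosomal genes had a median of 0.59 at percentile 100, with 12 of 39 higher, none lower and 27 neither, and a median of -0.13 with spike-in scaling. The cathepsin gene Ctsl was 4.42-fold higher, the asparaginyl endopeptidase gene Lgmn 4.19-fold and Gpnmb 6.79-fold. In the heme, iron and oxidative stress list, which holds targets of the related repressor Bach1, 7 of 34 members were higher, 2 lower and 25 neither, with a median of 0.38 at percentile 99.7 that was -0.34 with spike-in scaling. With quantile normalization the list no longer stood apart (median 0.18, percentile 97.3, or 0.15 and 96.2 after normexp). The transferrin receptor gene Tfrc was 9.56-fold higher, the phagosomal metal transporter gene Slc11a1 15.1-fold higher and the iron exporter gene Slc40a1 3.50-fold lower. Heme oxygenase 1 (Hmox1) differed by 0.64, which met neither condition and became -0.08 with spike-in scaling.

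Matrix-degrading and matrix genes had a median of 2.16, or 1.24 with bounded genes at their bound (percentile 100), with 12 of 23 higher, 2 lower and 9 neither. The median was 0.69 where all 4 arrays had to be above background, as several members were dim in WT, 1.09 with normexp and the 75th percentile, lower still with normexp and quantile normalization, and 1.44, with 11 higher and 4 lower, with spike-in scaling. In the same RNA 11 of 24 monocyte and interstitial macrophage markers and 4 of 9 endothelial markers were higher. Macrophage elastase (Mmp12) rose from -3.80 ± 0.04 to 2.60 ± 0.03, 84.0-fold. The gelatinase gene Mmp2, the membrane-bound metalloprotease gene Mmp14 and the thrombospondin gene Thbs1 were not well above background in WT and were at least 30.7-fold, 26.2-fold and 21.6-fold higher.

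Phagocytic and scavenger receptor genes changed in both directions, with 12 of 35 higher, 6 lower, 17 neither and a median of 0.32 at percentile 98.3, which was -0.39 with spike-in scaling. The percentile was 96.9 with no filter on dim probes and 94.8 where all 4 arrays had to be above background, so the list then did not stand apart. Mfge8, which bridges apoptotic cells to integrins, was 80.8-fold higher, the complement gene C1qa 17.0-fold higher and the integrin gene Itgb3 at least 176-fold higher by its brighter probe, with a difference of 1.74 for its other probe. The complement C1q genes belong to the monocyte and interstitial macrophage markers as well, of which 11 of 24 were higher. Antigen presentation genes included more lower than higher members, with 10 of 28 lower, 3 higher, 15 neither and a median of -0.05 at percentile 10.2, which was -0.19 with median centring and -0.77, with 1 higher and 11 lower, with spike-in scaling. The MHC class II genes H2-Aa (3.02 ± 0.06 and -0.31 ± 0.01) and H2-Ab1 were lower, H2-Ab1 by 7.26-fold, and the invariant chain gene Cd74 8.62-fold lower, whereas B2m, the light chain of class I, was 2.19-fold higher, a call lost with median centring (0.996) and spike-in scaling (0.41). Interferon response genes had a median of 0.79 (percentile 100), with 15 of 36 higher, 1 lower and 20 neither, which became a median of 0.07 with 5 higher and 2 lower under spike-in scaling. The antiviral genes Oasl2 and Rsad2 were 14.7-fold and 12.2-fold higher and the ISG15 protease gene Usp18 10.8-fold higher.

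**Figure D3:**
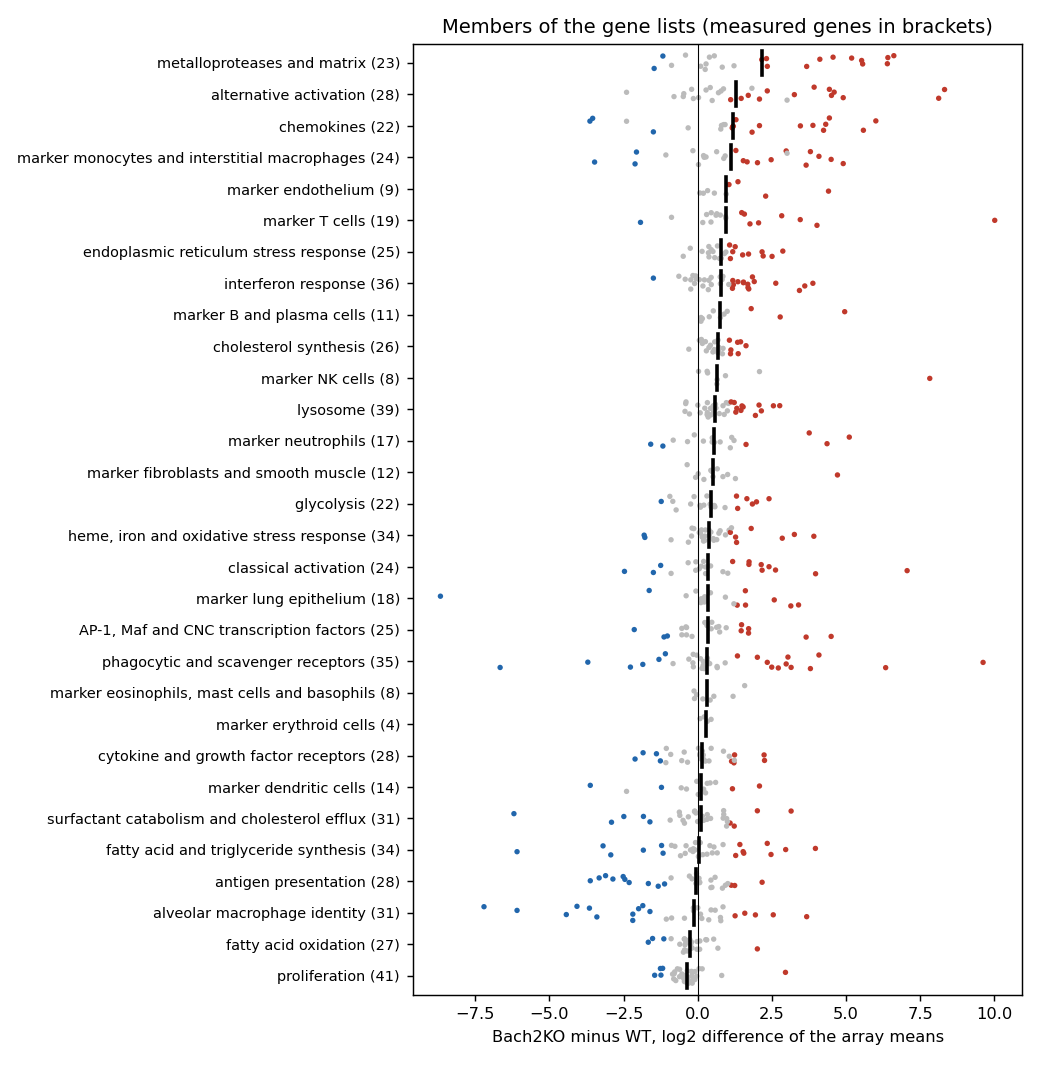
Log2 difference (Bach2KO minus WT, means of 2 technical arrays each) of every measured member of 30 fixed gene lists, red where called higher, blue where called lower and grey otherwise, with a black bar at each list's median and genes not well above background in a genotype drawn at their measured means. Medians run from -0.37 for proliferation to 2.16 for metalloproteases and matrix; spike-in scaling would move every point left by 0.72 and turn 8 medians that stood apart above 0 negative (classical activation, cholesterol synthesis, lysosome, heme and iron, AP-1 and Maf, phagocytic, glycolysis and neutrophils), with every positive median that did not stand apart.

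Markers of several other cell types also differed between the RNA samples. Monocyte and interstitial macrophage markers had a median of 1.10, or 0.96 with bounds (percentile 100), 0.39 with spike-in scaling and 0.64 where all 4 arrays had to be above background. The complement gene C1qc rose from -3.54 ± 0.04 to 0.26 ± 0.07. While 11 of 24 members were higher, 3 were lower, among them the chemokine receptor gene Ccr2 (4.33-fold). Of 19 T cell markers 8 were higher, 1 lower and 10 neither, with a median of 0.94 at percentile 100, against 4 higher and a median of 0.22 with spike-in scaling. The T cell receptor complex genes Cd3d and Cd3g were not well above background in WT and were at least 6.15-fold and 2.67-fold higher, calls of Cd3d and Cd3g that ended with normexp background correction (1.18 and 0.85). Of 17 neutrophil markers 4 were higher, 2 lower and 11 neither (median 0.56, percentile 99.2, 0.91 without WT array 1 and -0.16 with spike-in scaling). The calprotectin subunit gene S100a8 was 13.5-fold higher and its partner S100a9 at least 32.4-fold. Endothelial markers were higher for 4 of 9 and lower for none (median 0.96, percentile 99.7, and 0.24 with 1 higher under spike-in scaling), with the cadherin gene Cdh5 21.2-fold higher. B and plasma cell markers were higher for 3 of 11 and lower for none (median 0.76, percentile 97.8, and 0.05 with spike-in scaling), with the proteoglycan gene Sdc1 at least 8.92-fold higher. This list no longer stood apart without Bach2KO array 1 (95.9), without Bach2KO array 2 (95.6), or with normexp and the 75th percentile (96.0), no filter on dim probes (86.4) or all 4 arrays above background (92.7).

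The other marker lists did not stand apart from matched lists with the main settings, and with spike-in scaling each of their medians lay below 0. Of 8 NK cell markers 1 was higher, Klra8, a member of a family of near-identical receptors, at least 179-fold (median 0.65, percentile 97.0, and 98.2 without WT array 1). Lung epithelial markers had 6 of 18 higher and 2 lower (median 0.34, percentile 91.0, but 99.8 with the mean of a gene's probes, 99.1 with normexp and quantile normalization and 97.9 with all 4 arrays above background), with the podoplanin gene Pdpn 10.5-fold higher beside the lower Epcam. Of 12 fibroblast and smooth muscle markers 1 was higher, Pdgfra, at least 6.33-fold (median 0.50, percentile 91.0). Dendritic cell markers had 2 of 14 higher and 2 lower (median 0.11, percentile 50.4, below 0 also with median centring and quantile normalization). No member was called among 8 markers of eosinophils, mast cells and basophils (median 0.29, percentile 62.7) or 4 erythroid markers (median 0.27, percentile 73.0). In all, 20 of 32 lists stood apart, 17 above and 3 below, where the thresholds give a nominal 1.6 by chance. Lists share genes, and 8 of 100 unchanged lists stood apart in simulated data. Random and simulated lists were drawn without regard to genes that vary together. Members of a real list may vary together, so more than the nominal 1.6 lists may stand apart without an effect of genotype. How many was not estimated.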

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

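The tests of explanations in this part, and the comparison with spike-in probes, were chosen only after their results had been seen, whereas the marker lists and the normexp setting were fixed before.

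Among 8193 measured probes without a gene symbol, which the comparison did not use, 375 were at least 2-fold higher in each array pair and 565 lower. Lower calls thus outnumbered higher ones among these probes, unlike among the genes with a symbol. No explanation was tested for these probes.

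The E1A spike-in probes, which the main scaling did not use, were 0.72 higher relative to the sample RNA in Bach2KO (SD 0.15 over 9 probes, 0.45 to 0.89). A few abundant transcripts taking up the signal would leave less for the rest, but the 100 brightest probes took 1.505 percentage points more of the summed signal in Bach2KO, which argues against that as the whole cause. Less sample RNA per spike-in during labelling may have shifted all spike-ins alike. The shift differed by 0.22 between the brightest and the dimmest spike-in probe, which leaves this open. No biological explanation was tested, because whether spike-ins were added per cell or per amount of RNA is not given in the sources used here.

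Of 11 marker lists of other cell types 5 stood apart above matched lists in the Bach2KO RNA, although the neutrophil median turned to -0.16 with spike-in scaling and the B and plasma cell list did not stand apart without either Bach2KO array (95.9 and 95.6) or in 3 other settings. T cells among the sorted cells, which a gate not given here might remove, are a candidate source for 8 of 19 T cell markers (14 of the 19 above background in both genotypes), but Cd3d had a log2 signal of -3.73 in Bach2KO, and Cd3e, named after its value was seen, differed by 0.17. Neutrophils are a candidate source for 4 of 17 markers (3 of the 17 in other lists too), with S100a8 and S100a9 at 4.202 and -1.33 in Bach2KO, while 2 were lower. A lower share of alveolar macrophages would raise all other types alike, and the medians of 10 marker lists spanned 0.69, less than the 0.78 median interquartile range within a list. None of these was excluded, and expression of these genes by macrophages without Bach2 stays open as well.

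Alveolar macrophage genes were lower together with higher monocyte and interstitial macrophage genes. Dilution by other cells would lower all identity genes by about the same amount, whereas 5 of 31 were at least 2-fold higher beside 11 lower, and Fabp1 differed by -7.21 where Pparg differed by -0.10, which argues against dilution as the whole cause. Another macrophage population in the Bach2KO gate may bring monocyte and interstitial macrophage markers, 11 of which were higher of 24 and 3 lower, and it cannot be told apart from altered expression in alveolar macrophages because bulk RNA of a sort was measured. Of these markers 14 are in other lists as well, and of the 10 that are not, 5 were higher and 2 lower. The chemokine receptor gene Ccr2 was among the 3 lower markers, at 4.33-fold.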

How the results depend on the processing

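The spike-in scaling and the crossed block were chosen after seeing the data, the other alternatives before. Against 1266 higher and 892 lower genes, normexp with quantile normalization gave 836 higher. Spike-in scaling gave 628 higher and 3192 lower, because it lowered every difference by 0.72, which left the percentiles of the lists unchanged. A threshold of 1.5-fold gave 2237 higher and 1933 lower and one of 3-fold 695 and 410, by construction. Requiring a 2-fold difference beside the limma adjusted p under 0.05 left 2586 genes of 9784. The other settings kept both counts within 1.5 times of the main ones. Leaving out each array in turn gave 1328 to 1490 higher and 968 to 1035 lower genes and 6967 to 8720 past limma, the lone array being assumed to vary like the other genotype. The replicate number as a block left 8132 genes past limma. The numbers mark parts of 1 RNA sample each and pair nothing across genotypes. Same-numbered arrays deviated with r = -0.14 across genes, which are not independent replicates, and the crossed pairing as a block gave 10366. Between 18 and 22 lists stood apart in each setting, against 20, and 16 of the 20 did so in every setting. Those that lost their standing in some setting were B and plasma cells, phagocytic receptors, heme and iron, and classical activation, and those that gained it were lung epithelium, NK cells and sex-linked genes, with values given beside each list. Normexp with quantile normalization lowered medians by over 1.5 times for lists that still stood apart, among them alternative activation (0.76), interferon response (0.48), monocytes (0.43), T cells (0.43), endothelium (0.38), glycolysis (0.26) and neutrophils (0.23), and the cause was not tested. Median centring, which lowered every difference by the same amount, left medians of 0.20 for AP-1, Maf and CNC factors, 0.21 for classical activation, 0.19 for phagocytic receptors and 0.25 for heme and iron. Of list medians above 0, 18 were below 0 with spike-in scaling, for the same reason as above, and 8 of these belonged to lists that stood apart: classical activation -0.37, cholesterol synthesis -0.038, lysosome -0.13, heme and iron -0.34, AP-1, Maf and CNC factors -0.38, phagocytic receptors -0.39, glycolysis -0.29 and neutrophils -0.16. Apart from these 8, list medians moved by less than the technical SD in 254 comparisons and by more in 186. Named genes kept their call in 2256 comparisons, lost it in 71 and gained it in 7, and none reversed. Another 29 named genes had no value where all 4 arrays had to be above background. Of the lost calls, 15 were under normexp with quantile normalization, 12 under normexp with the 75th percentile, 16 under spike-in scaling and 19 at 3-fold. Esam lost its call without WT replicate 2 (2.70) and without Bach2KO replicate 1 (2.21), and Eif2s3y gained one without WT replicate 2 (-1.13). Signal over background limits the dim genes: 309 of the calls rest on a bound.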

Other observations

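The test of Bach2's neighbours was chosen after its result had been seen; the gene lists were fixed before the data were examined.

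Genes of the endoplasmic reticulum and amino acid stress response were higher in the Bach2KO RNA, with 10 of 25 measured members higher, none lower and a median of 0.79 at percentile 100, against 4 higher, 1 lower and a median of 0.07 with spike-in scaling. Trib3, a pseudokinase induced by Atf4, was 7.30-fold higher, asparagine synthetase (Asns) 5.68-fold and the eIF2 alpha phosphatase subunit gene Ppp1r15a 4.61-fold. Glycolysis genes had 6 of 22 higher, 1 lower and a median of 0.43 at percentile 99.9, which was -0.29 with spike-in scaling. The glucose transporter gene Slc2a1 rose from 0.12 ± 0.16 to 2.52 ± 0.08 (SD, n = 2 arrays), 5.29-fold, and the phosphofructokinase gene Pfkl was 3.95-fold higher. Proliferation genes were lower as a group, with a median of -0.37 at percentile 0.08, and of 41 members 4 were lower and 1 higher, against 18 lower, 1 higher and a median of -1.09 with spike-in scaling. The kinesin gene Kif11 and the checkpoint kinase gene Bub1b were 2.39-fold and 2.36-fold lower, calls that ended with normexp background correction, and the higher member was the cyclin gene Ccnd1 at 7.77-fold, beside Ccnd2 at 2.74-fold lower.

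The list of AP-1, Maf and CNC transcription factors holds relatives and dimer partners of Bach2, and also Prdm1, Irf4 and Irf8, which belong to other families. Of its 25 measured members 6 were higher and 3 lower, Prdm1 among the lower. The median was 0.34 at percentile 99.3, and -0.38 with spike-in scaling. Maf, not well above background in WT, was at least 7.26-fold higher, and it is also among the monocyte and interstitial macrophage markers, of which 11 of 24 were higher. The AP-1 repressor gene Jdp2 was 3.28-fold higher, a call that ended with spike-in scaling. Prdm1, which encodes the repressor Blimp-1 and is a known target of Bach2 in B cells, was 4.41-fold lower. Loss of a repressor would raise a target instead, and whether Bach2 acts on Prdm1 in these cells was not tested. Cytokine and growth factor receptors did not stand apart, with 5 of 28 higher, 4 lower and a median of 0.13 (percentile 65.8), which was -0.59 with spike-in scaling and just below 0 with median centring. The interleukin 33 receptor gene Il1rl1 was 4.71-fold higher, a call that also ended with normexp, and the interleukin 6 receptor gene Il6ra 3.59-fold lower. None of 4 sex-linked genes was called (median -0.64, percentile 3.18), whereas all 4 were called lower with spike-in scaling (median -1.36). The Y-linked Ddx3y and Eif2s3y differed by -0.50 and -1.06. Whether the pools held different shares of male mice was not tested. The sex-linked list stood apart below with quantile normalization, with no filter on dim probes (percentile 2.03) and with the mean of a gene's probes (median -0.94, percentile 0.70). Of 14 reference genes 1 was higher, B2m, with a list median of 0.20 (percentile 67.0) that was -0.52 with spike-in scaling and also negative with quantile normalization.

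Strain variants carried along with a targeted locus would be a source of differences beside Bach2. Of the 40 measured genes nearest to it in the RefSeq table, 4 were changed, all 4 higher (Ggh, Fhl5, Epha7 and Rragd, named after their values were seen). That share (exact 95% binomial interval 2.79 to 23.7%) compares with 14.3% of all genes, so no excess around the locus was seen and the upper limit lies below 2 times the share over all genes. Single genes among them stay open.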
